A study of Mus musculus with 2 samples.

How the data were processed

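Transcripts of mouse gastrocnemius were measured by long-read RNA sequencing in 2 biological replicates of 1 group (male B6CASTF1/J mice, 36 days of age, 2 µg of RNA each). The labels name the animals as male 03 (replicate 1) and male 04 (replicate 2) and give both the same donor entry, and they name Lexogen SIRV and Ambion mix 1 spike-ins. The deposited tables give read counts per transcript model for each library, raw and not pooled, and list models with at least 1 read. They were checked to be whole numbers with different totals. Per the file headers, reads were on assembly mm10 and were assigned with the GENCODE M21 annotation, and the annotation files name TALON as the source of unannotated models. The aligner and the version of TALON are not given in the sources used here. The deposited tables also hold the length and exon number of each model, and the deposited annotation files hold 1-based exon positions.

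Each table sorts models into annotated, incomplete match (part of an annotated transcript), new combination of annotated splice sites, new junction, antisense, intergenic and genomic. Gene counts were sums over all models of an annotated gene. Spike-in models were left out of totals, and held 3.68% and 2.42% of all reads. All spike-in entries with reads in the tables were of the Ambion set, so the spike-in share and slope rest on that set alone. Models outside annotated genes held 2.79% and 7.00% of mouse reads and were left out of gene counts. CPM were counts scaled to 1e6 of each library's reads in annotated genes. Models under 50 bases, some listed at 1 base, held 0.637% and 2.30% of mouse reads and were kept. Models with a single read made up 60.5% and 58.0% of models.

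The tests, gene lists and alternatives were fixed before the data were examined. With 1 library on each side there was no residual degree of freedom for edgeR's quasi-likelihood test, so each gene with at least 10 reads in sum was tested with a two-sided exact conditional binomial test of its 2 counts given the library totals. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold, with 0.5 reads added for log2 ratios. Agreement was the Pearson and Spearman correlation of log2(CPM + 1) with 1000 bootstrap draws over genes, and a chi-square against read counting alone. The between-library coefficient of variation came from edgeR 4.0.16 (common dispersion, intercept only, TMM), with an interval from 100 resamples of genes. The deviations for that interval came from another common-dispersion estimator of edgeR, which gave 0.398, and were added to the reported value. Size factors came from DESeq2 1.42.0, in R 4.3.3. Shares carry Wilson 95% intervals per library, and ratios of counts exact binomial ones. List medians were set against 10000 random lists of the same size, matched on mean expression in 20 bins, for the 24 of 26 lists with at least 3 tested members. The level and difference of 1 list are left out of the text because they need a withheld item. The satellite cell and Y-linked lists had 2 tested members each, with 0 called by the exact binomial test (1 at an unadjusted p under 0.05) and 1 called.

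The share of the leading isoform was compared with a two-sided Fisher exact test in genes with at least 50 reads in each library, with Benjamini-Hochberg adjustment. Models were matched between the libraries by their chain of splice junctions, and unannotated single-exon models of a gene were joined into 1 group wherever they overlapped in a chain, so a single-exon leading isoform is such a group and its class and length are those of its largest model. An earlier match that also required the same class was dropped after its results were seen, because the tables give some structures different classes. Of 29919 models in both libraries, 2053 had another class in the other table, 941 of them with more than 1 exon, with 1.80% and 1.57% of gene reads. Class shares and counts restricted to some classes carry this difference. An unannotated model counted as found in both libraries only if both tables put it in the new-combination or new-junction class.

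The length of a gene was that of its leading annotated, new-combination or new-junction model. It was first taken from annotated models alone and was changed after the data were seen, since the annotated reads of Atp2a1 (2 and 1) were in a short model; both versions were run. The trend on length was a lowess curve (fraction 0.3) over genes with at least 50 reads, and slopes carry intervals from 1000 bootstrap draws. Spike-ins with at least 10 reads in sum entered their own slope, with a permutation test of 100000 draws. The share of incomplete matches, among reads in annotated, incomplete, new-combination and new-junction models, was binned by 1000 bases of the longest annotated model with reads. For exons that no annotated junction skips, reads kept an exon when they held it with its annotated ends and skipped it through an unannotated junction, and exons with at least 50 such reads entered. Atp2a1 was left out of that test.

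Genes named in the text were all members of the fixed lists, the 20 genes with the highest mean CPM, the 10 called genes with the largest fold in each direction among those with at least 50 reads in sum, the splicing panel, the 10 unannotated models with the most reads in both libraries, the 10 largest differences in leading isoform share and the 10 antisense or intergenic loci with the most reads. Gm12671 and the short exons of Hacd1, Ik, Rnf5, Sugt1 and Trdn were named after their values were seen, as was the comparison of pseudogenes with the models beside them. Intergenic and pseudogene reads were taken as the tables assign them.

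Alternatives were TMM and DESeq2 scaling, no filter on low counts, other pseudocounts, adjusted p alone, counts restricted to annotated, new-combination and new-junction models, other bins and read minimums, and each replicate alone. Correction for the length trend, the restriction to genes with a length and leaving Myh4 out of the length bins were added after the data were seen. A list median counted as moved when it shifted by more than the SD of its random lists, a correlation or coefficient of variation when it left its bootstrap interval, a count of genes, models or lists when it changed by more than 1.5 times, and other values when they shifted by more than 1 SD between replicates.

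The steps were tested on simulated data. For genes differing between the libraries, drawn for 8032 tested genes, the binomial test called 43.5% of genes changed 2.5-fold, 59.1% of those changed 4-fold, 84.4% of those changed 8-fold and 0 of 7833 unchanged genes. For leading isoform shares over 1834 genes, 18.4% of shifts of 10 points and 89.7% of shifts of 30 points were called, and 1 of 1634 unchanged genes. Both of these draws held counting error only, without the further spread between the real libraries. Their low counts of false calls therefore do not carry over to the calls made here. Leading shares before any shift were drawn at lower values than the measured medians of 82.58% and 75.65%. For list differences over 8339 genes, 2 of 100 unshifted lists of 10 genes and 86 of 100 lists shifted by 1 on the log2 scale lay outside the central 95%. Simulated coefficients of variation of 0.2 and 0.5 came back as 0.204 and 0.495. Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.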

Results

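Long-read RNA sequencing measured the transcripts of the gastrocnemius, a calf muscle, in male B6CASTF1/J mice, the first-generation cross of C57BL/6J and CAST/EiJ, at 36 days of age. The labels give 1 group with 2 biological replicates, each made from 2 µg of RNA, so the design holds no comparison of conditions. Replicate 1 held 1106945 reads in 72469 transcript models and replicate 2 held 1514119 reads in 88667 models. Of these, 1066170 and 1477435 reads were from the mouse and the rest from spike-in RNAs. Annotated genes took 1036455 reads (97.2% of mouse reads) in replicate 1 and 1374068 (93.0%) in replicate 2, and these are the totals behind CPM, the counts scaled to 1e6 reads. A count of 0 allows up to 2.89 CPM in replicate 1 and 2.18 CPM in replicate 2. Reads carried no molecular identifiers in the tables used here, so intervals and floors cover counting error only. Values are means ± SD over the 2 replicates unless stated, and positions are on mm10.

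The first question was which genes the muscle expressed most. Creatine kinase Ckm (ENSMUSG00000030399.2, chromosome 7, 19404776 to 19422841) had the highest mean, 70108 ± 6096 CPM (SD, n = 2), and the highest level in replicate 2, while Atp2a1 and Acta1 were above it in replicate 1. Skeletal actin Acta1 (ENSMUSG00000031972.5, chromosome 8, 123891769 to 123894751) followed with 69018 ± 12455 CPM. The calcium pump gene Atp2a1 (ENSMUSG00000030730.12, chromosome 7, 126445858 to 126463108) came next with 63213 ± 52607 CPM, since it took 10.04% of reads in replicate 1 and 2.60% in replicate 2. These 3 genes held 25.3% of gene reads in replicate 1 and 15.2% in replicate 2. Next came the troponin C gene Tnnc2 with 43581 ± 12648 CPM, tropomyosin Tpm1 with 27121 ± 336 CPM, and the myosin light chain genes Mylpf with 27117 ± 5717 CPM and Myl1 with 24109 ± 6951 CPM. Myh4, Slc25a4, Aldoa, Eno3, Ldha, Pgam2, Actn3, Casq1, Atp5b, Tnni2, Tcap, Cox4i1 and Ak1 filled ranks 8 to 20, from 15301 ± 1743 CPM for Myh4 to 5393 ± 1074 CPM for Ak1. The 20 genes together held 45.8% and 40.8% of gene reads.

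The next question was the fibre composition as read from the myosin heavy chain genes. Myh4, the type 2B gene (chromosome 11, 67238029 to 67260446), held 82.3% of sarcomeric myosin heavy chain reads in replicate 1 (Wilson 95% interval 81.7 to 82.9; 17718 reads) and 95.0% in replicate 2 (94.7 to 95.3; 23911 reads), a mean of 88.7% ± 8.99. Myh1, the type 2X gene, held 14.7% (14.2 to 15.2) and 3.15% (2.94 to 3.38), a mean of 8.91% ± 8.14. Myh2, the type 2A gene, held 1.98% ± 0.780 and the slow gene Myh7 0.415% ± 0.0363. Embryonic Myh3 had 7 and 2 reads and neonatal Myh8 had 4 and 2. Myh6 had 1 read in replicate 1, Myh7b had 1 read in replicate 2, and Myh13 had 0, which allows up to 0.0169% and 0.0125% of the myosin reads. A single 3-exon model of 460 bases at the 3′ end of Myh4, an incomplete match to the annotation (67259083 to 67260446), held 831 of the Myh4 reads in replicate 1 (5.70%) and 14332 in replicate 2 (63.1%). Without incomplete and genomic models, Myh4 held 78.6% of myosin reads in replicate 1 and 84.3% in replicate 2. In those counts Myh1 held 18.8% and 11.5%, and Myh2 held 1.90% and 2.63%, against 2.53% and 1.43% with all models, so its direction between the libraries was left open.

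Fast genes exceeded their slow paralogues in all 10 pairs in both libraries. The mean log2 ratio was 10.11 ± 0.89 (SD, n = 2) for Atp2a1 over Atp2a2, 8.50 ± 0.31 for Mylpf over Myl2, 8.45 ± 0.87 for Tnnc2 over Tnnc1 and 7.74 ± 0.27 for Myh4 over Myh7. It was 7.58 ± 0.56 for Casq1 over Casq2, 7.54 ± 0.88 for Tpm1 over Tpm3, 7.35 ± 0.57 for Myl1 over Myl3, 7.33 ± 0.56 for Tnni2 over Tnni1 and 4.90 ± 0.36 for Myoz1 over Myoz2. The pair Tnnt3 over Tnnt1 had the smallest ratio, 2.81 ± 1.17. Of the Tnnt1 reads, 91.5% ± 5.67 sat in a 3-exon model of 776 bases that matched the annotation in part, and with annotated, new-combination and new-junction models alone this pair had a mean log2 ratio of 6.80. Except for Myh4 over Myh7, each ratio was lower in replicate 2 than in replicate 1, and with annotated, new-combination and new-junction models alone that pair was lower there too (6.83 and 5.81). No test was made between genes, since there are 2 libraries of 1 group.

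**Figure D1:**
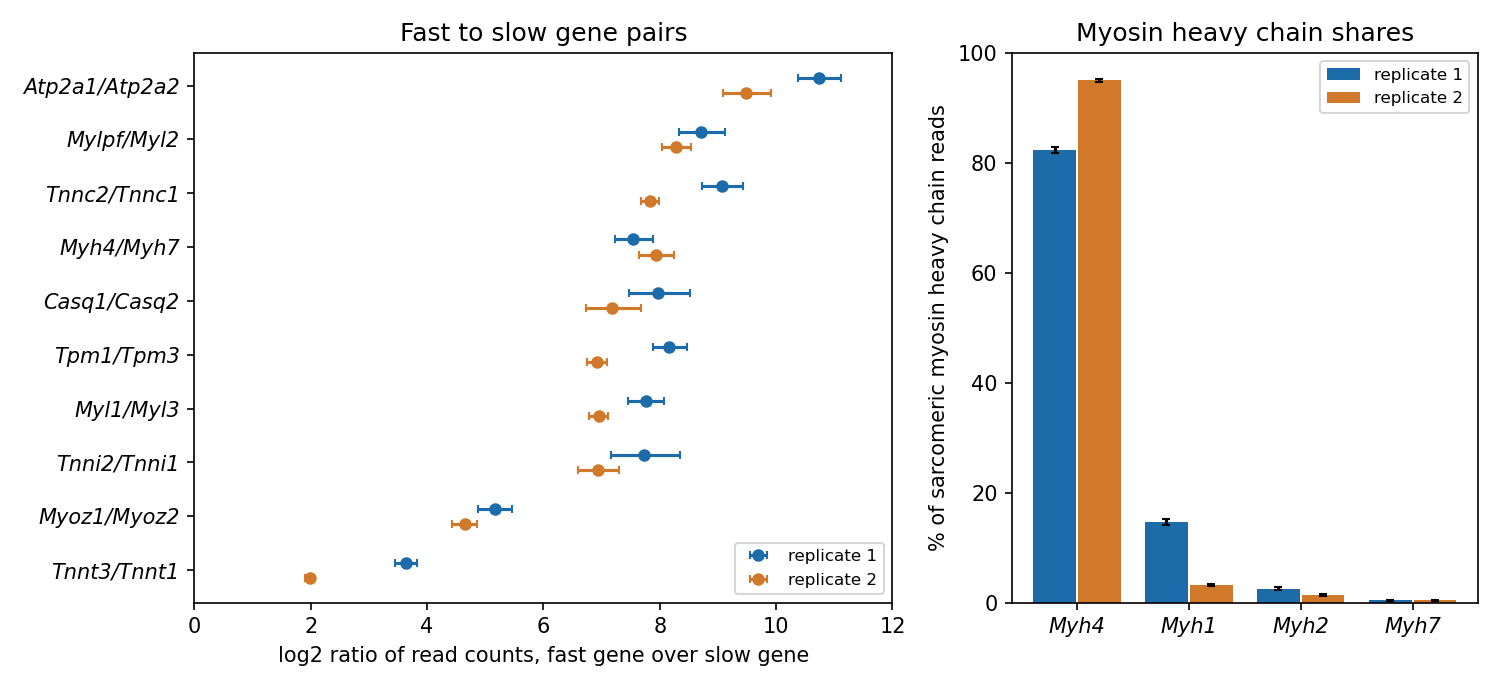
Left, log2 ratio of the read counts of each fast gene over its slow paralogue, with 1 point per replicate and exact 95% binomial intervals; right, share of sarcomeric myosin heavy chain reads in % per replicate with Wilson 95% intervals, from 0. All 10 ratios lie above 0 in both replicates, and Myh4 holds 82.3% and 95.0% of the myosin reads.

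Summed levels of gene lists, fixed before the data were examined, described the tissue. The fast sarcomere genes summed to 162629 ± 20646 CPM (SD, n = 2) and the slow sarcomere genes to 1670 ± 1005 CPM. Sarcomere structure genes summed to 152401 ± 14926 CPM, calcium handling genes to 85857 ± 49360 CPM, glycolytic genes to 51661 ± 1219 CPM and nuclear genes of oxidative phosphorylation to 31857 ± 11940 CPM. The myosin heavy chain list summed to 17248 ± 217 CPM, developmental muscle genes to 1318 ± 193 CPM (mostly Actc1 and H19), fat metabolism genes to 4686 ± 378 CPM and cytosolic ribosome genes to 3808 ± 489 CPM. Mitochondrially encoded genes summed to 2795 CPM in replicate 1 and 13266 CPM in replicate 2. Gapdh had 64.6 and 94.6 CPM in the deposited counts, against 13816.9 ± 632.3 CPM for Aldoa. The Gapdh count is uncertain, and so is its part in the glycolytic sum. The annotation holds pseudogenes named after it, such as Gapdh-ps15, but the 35 and 84 reads there do not account for the gap from Aldoa. Whether Gapdh reads were placed on pseudogenes was not tested.

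Genes of other cell types and states were summed next. Matrix and fibroblast genes summed to 4255 ± 3116 CPM, led by Gsn (1835 and 628 CPM), Col3a1 (1500.3 and 337 CPM) and Col1a1 (1306 and 254 CPM). Tendon genes summed to 286 ± 59.6 CPM, blood genes to 316 ± 61.8 CPM, adipocyte genes to 280.4 ± 177 CPM, smooth muscle and pericyte genes to 197 ± 90.0 CPM, endothelial genes to 129 ± 24.3 CPM and immune genes to 129 ± 37.8 CPM. Satellite cell genes summed to 32.7 ± 16.5 CPM, and Pax7 had 0 reads in both libraries. Neuromuscular junction genes summed to 97.3 ± 27.5 CPM, immediate early and stress genes to 121 ± 77.9 CPM, atrophy genes to 686 ± 381 CPM, clock genes to 241 ± 8.95 CPM and Y-linked genes to 77.5 ± 20.0 CPM. Some members, such as Gsn and Sparc, are not exclusive to 1 cell type, and no cell type was counted.

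The replicates were then compared with each other across genes. Of 15508 genes with a read in either library, 11810 had reads in both, 1604 in replicate 1 alone and 2094 in replicate 2 alone. Across the 8339 genes with at least 10 reads in sum, Pearson's r of log2(CPM + 1) was 0.868 (95% bootstrap interval 0.860 to 0.876) and Spearman's rho was 0.828 (0.819 to 0.836), where genes are not independent replicates. A chi-square against read counting alone was 203831 on 8338 degrees of freedom, or 24.5 per degree, which says only that these are separate samples. The edgeR coefficient of variation between the libraries beyond counting error was 0.394 (interval 0.387 to 0.404). That interval covers the choice of genes, not the uncertainty of a spread taken from 2 libraries.

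Genes that differed between the libraries included Cish, Slc25a25, Gadd45g, Cebpd, Mbp and Gbp7, which were higher in replicate 1. Cish (chromosome 9, 107296026 to 107302784) had 62 and 4 reads, Slc25a25 had 293 and 39, Gadd45g had 207 and 32, Cebpd had 126 and 21, Mbp had 507 and 90 and Gbp7 had 42 and 9. Their log2 ratios of replicate 2 over replicate 1 were −4.20, −3.30, −3.08, −2.96, −2.89 and −2.57, with adjusted p from 2.03e-97 (Mbp) to 2.73e-07 (Gbp7) in the exact binomial test with Benjamini-Hochberg adjustment. The test called 1458 of 8339 genes at an adjusted p under 0.05 and at least 2-fold, 461 higher in replicate 2 and 997 higher in replicate 1, and 3161 genes had an unadjusted p under 0.05. It compares these 2 libraries, not conditions or animals in general, and the difference has no replicate check. The median log2 ratio of all tested genes was −0.28, and scaling by TMM shifted ratios up by 0.26 to a median of −0.02. The share of calls higher in replicate 2 was 31.6% with total counts, 59.6% with TMM and 61.1% with DESeq2 size factors.

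The other 4 of the 10 genes with the largest ratios toward replicate 1 were processed pseudogenes. Oaz1-ps had 98 and 11 reads, Gm13394 had 307 and 48, Gm12033 had 1216 and 209, and Vcp-rs had 50 and 7. For the first 3, replicate 2 held reads in single-exon models that began on the last base of the pseudogene and were assigned elsewhere: 148 reads in AC154200.1 beside Oaz1-ps, 545 in Cfap77 beside Gm13394 and 1584 in an intergenic locus beside Gm12033. No such read was listed in replicate 1. With these reads added, the log2 ratios were 0.29 for Oaz1-ps, 0.54 for Gm13394 and 0.15 for Gm12033. Vcp-rs also adjoined a single-exon model, with 101 and 64 reads, and its log2 ratio was −1.49 with them added, against −3.16 without. That addition was chosen after the values were seen. Reads of these near-identical copies are uncertain in their gene of origin.

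Among the 10 genes with the largest ratios toward replicate 2, all but Gm6563 were led in that library by a genomic or an incomplete model. Cfap77 had 0 and 546 reads, 137-fold higher in replicate 2 against a floor of 3 counts per library. The exact 95% lower bound of its ratio was 111. Of its reads in replicate 2, 545 sat in a 182-base genomic model (chromosome 2, 28933429 to 28933610). They are the reads beside Gm13394 given above, where the log2 ratio with both added was 0.54. Usp50 had 2 and 429 reads (95% interval of the ratio 44.5 to 1340.3), of which 425 sat in a 259-base genomic model. AC154200.1 had 0 and 148 reads (37.2-fold higher against that floor, exact lower bound 29.9). They are the reads beside Oaz1-ps given above, where the log2 ratio with both added was 0.29. Gm6829 had 0 and 171 reads (43.0-fold higher against that floor, exact lower bound 34.6). Gm20716, Gm49356, Bmpr2, Gm15856, Platr31 and the processed pseudogene Gm6563 made up the rest, with 51 to 116 reads in replicate 2. Of the 461 genes higher in replicate 2, genomic models led 38.8% and incomplete models 15.0%, against 3.81% and 3.71% of the 997 genes higher in replicate 1. Of the 1458 calls, 987 (67.7%) were also made when annotated, new-combination and new-junction models alone were counted, 982 of them in the same direction.

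Called genes differed in transcript length. The median length was 1110.5 bases among genes higher in replicate 2 and 3423 bases among those higher in replicate 1, against 2448 bases among all tested genes. The length was known for 86.8% and 99.7% of the called genes. Across 3744 genes with at least 50 reads, the log2 ratio fell by 0.42 per doubling of length (95% bootstrap interval of the slope −0.45 to −0.39). The median log2 ratio was 0.82 for the 113 genes under 500 bases and −0.67 for the 504 genes of 3000 to 4000 bases. The fall did not go on above that length. The median was −0.63 for the 431 genes of 4000 to 6000 bases and −0.50 for the 163 longer ones. When ratios were corrected for this trend, a setting chosen after the data were seen, 699 of 8120 genes were called, 445 higher in replicate 2 and 254 higher in replicate 1. The correction subtracts the curve with its overall level, so it also recentres ratios as TMM does. The turn of calls toward replicate 2 is therefore not specific to length.

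**Figure D2:**
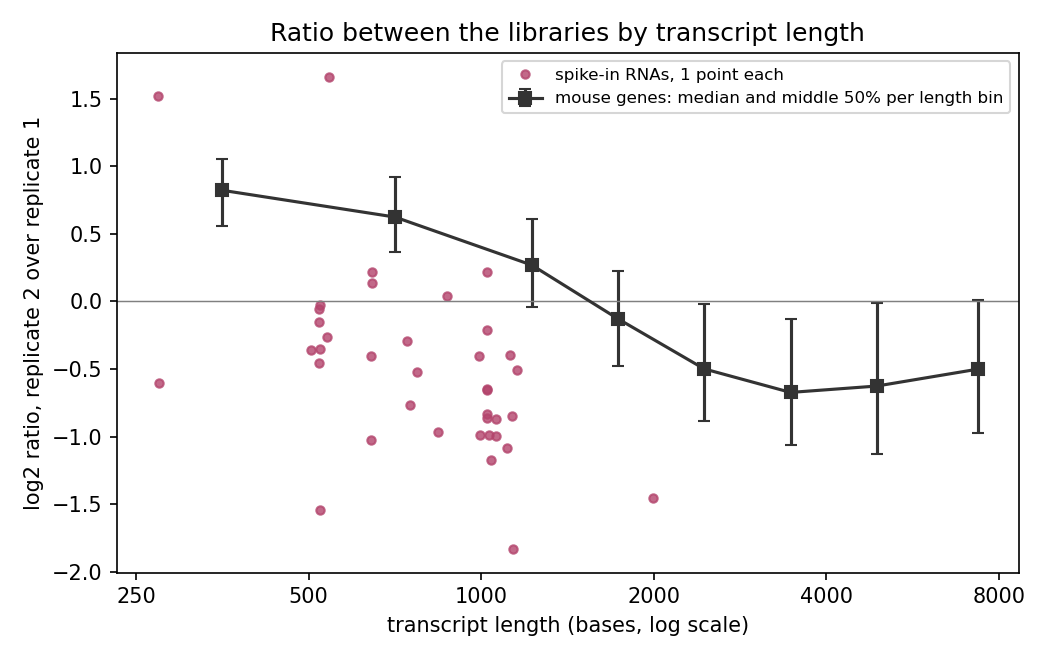
Log2 ratio of replicate 2 over replicate 1, each scaled to its reads in annotated genes, by transcript length in bases on a log axis. Squares are medians of mouse genes per length bin with bars for the middle 50% of genes, and each dot is 1 of 38 spike-in RNAs; the gene medians go from 0.82 in the shortest bin to −0.50 in the longest.

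The lists showed which groups differed between the libraries. All 12 tested mitochondrially encoded genes were higher in replicate 2, with a median log2 ratio of 2.15 and mt-Cytb at 2.78 (884 and 8043 reads). Of the slow sarcomere genes, 5 of 11 were called higher in replicate 2 (Tnnt1, Tnnc1, Myl3, Tpm3 and Tnni1), and the list's median was 0.86. Fabp4 and Cfd were called among 5 adipocyte genes, with a list median of 1.36. Toward replicate 1, 7 of 10 matrix and fibroblast genes were called (Col1a1 at −2.36, Col3a1 at −2.15, Col6a1, Fn1, Gsn, Col1a2 and Sparc), and the list's median was −1.49. The immediate early and stress list, shortened to immediate early genes below, had a median of −1.55 with 4 of 8 called (Hspa1a, Atf3, Junb and Jun). Atrophy genes had a median of −1.29 with 5 of 9 called (Ddit4, Mt2, Mt1, Myog and Trim63), or 7 adjusted over the list alone. Adipocyte calls went from 2 to 3 adjusted over the list alone, the splicing panel from 11 (5 higher in replicate 2, 6 higher in replicate 1) to 13, and the counts of the other lists were the same adjusted over the list alone.

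These lists and the splicing panel (median −0.43) were among the 8 of 24 lists whose medians lay outside the central 95% of 10000 random lists of the same size matched on expression. The percentiles, as descriptions of these libraries, were 100 for the mitochondrial list, 99.9 for slow sarcomere genes, 99.8 for adipocyte genes, 0 for matrix genes, 0.08 for immediate early genes, 0.095 for atrophy genes and 0.47 for the splicing panel. The direction of all 8 medians was the same under TMM. Of the nuclear oxidative phosphorylation genes, 5 of 17 were called higher in replicate 2 (Cox7a1, Ndufa4, Cox4i1, Cox6a2 and Ndufb8), and the list's median of 0.73 lay at percentile 90.1. Glycolytic genes had 0 of 15 called in the exact binomial test, with 13 at an unadjusted p under 0.05 but none of those 2-fold apart, and a median of −0.09, which was 0.16 under TMM and −0.68, at percentile 0.475 and outside the random range, with annotated, new-combination and new-junction models alone. Immune genes had 0 of 6 called and blood genes 0 of 4, with 0 and 2 at an unadjusted p under 0.05 in that test. The fast sarcomere list had 3 of 13 called, all higher in replicate 1 (Mybpc2, Actn3 and Myh1), and a median of −0.03 that was 0.23 under TMM. In the calcium handling list, Hrc (2.10) and Trdn (1.05) were higher in replicate 2 and Atp2a1 (−1.95) and Srl (−1.43) higher in replicate 1. Incomplete matches held 81.26% of Trdn reads in replicate 1 and 91.65% in replicate 2. A 432-base model among them had 411 and 1930 of the 1163 and 3184 Trdn reads, so this difference rests largely on partial models. The medians of the other lists were −0.48 for myosin heavy chains, −0.52 for developmental genes, 0.25 for sarcomere structure, −0.01 for calcium handling, −0.17 for fat metabolism, 0.34 for the cytosolic ribosome, 0.04 for endothelial, −0.71 for tendon, 0.45 for blood, −0.63 for immune, −1.06 for smooth muscle and pericyte, −0.58 for neuromuscular junction and −0.34 for clock genes.

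Removal of the length trend, a correction chosen after the data were seen, ended part of these calls in the exact binomial test with Benjamini-Hochberg adjustment. Because it also recentres ratios, calls lost toward replicate 1 cannot be put down to length alone. All 5 oxidative phosphorylation genes fell under 2-fold (log2 ratios of 0.35 for Ndufb8 to 0.62 for Ndufa4, from 1.02 and 1.33), while Atp5b (0.95 to 1.20) and Cycs (0.73 to 1.36) were called. Among slow sarcomere genes Tnnt1 (1.95) and Tnnc1 (1.18) stayed called, Myl3, Tpm3 and Tnni1 went to 0.90, 0.87 and 0.69, Csrp3 was called higher in replicate 1 (−0.95 to −1.49), and the median was 0.42. Among matrix genes Col1a1 (−1.78), Col3a1 (−1.56), Col6a1 and Gsn stayed called, Col1a2 (−0.79) and Sparc (−0.65) fell under 2-fold, Fn1 (−1.05) had an adjusted p of 0.226 in that exact binomial test with Benjamini-Hochberg adjustment, and the median was −0.90. Of the immediate early genes 0 of 8 stayed called: Jun went from −1.42 to −0.78, and Hspa1a (−2.28 to −1.68), Junb (−1.68 to −1.50) and Atf3 (−1.75 to −1.46) stayed over 2-fold and had adjusted p of 0.131, 0.0685 and 0.156 in that exact binomial test with Benjamini-Hochberg adjustment. Their median was −1.12 at percentile 0.1, but lay at percentile 10.6, inside the random range, when annotated, new-combination and new-junction models alone were counted. Mybpc2 (−0.72), Actn3 (−0.77), Srl (−0.91), Trim63 (−0.77) and Cfd also fell under 2-fold, and 11 of the 12 mitochondrial genes, 4 of 9 atrophy genes and 1 of 5 adipocyte genes (Fabp4) stayed called.

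Some medians changed sign with the setting. Under TMM the median was 0.08 for fat metabolism and 0.24 for calcium handling genes. With annotated, new-combination and new-junction models alone it was −0.46 for sarcomere structure, 0.77 for developmental and 0.07 for fast sarcomere genes. Among members with at least 50 reads it was 0.32 for clock and 0.01 for glycolytic genes. With the length trend removed it was −0.21 for cytosolic ribosome, −0.23 for blood, 0.40 for clock, 0.10 for myosin heavy chain, 0.31 for developmental, 0.19 for calcium handling, 0.13 for glycolytic and 0.24 for fat metabolism genes. The direction of these lists was left open.

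Other lists lay outside the random range in a single setting each or in a pair of them. With annotated, new-combination and new-junction models alone these were myosin heavy chains (−2.16, percentile 0), calcium handling (−1.18, percentile 0.04), glycolytic (−0.68, percentile 0.475) and tendon genes (−1.52, percentile 1.38). With the length trend removed they were fast sarcomere (−0.22, percentile 1.31), sarcomere structure (0.59, percentile 99.2), tendon (−0.68, percentile 1.36) and immune genes (−0.78, percentile 1.63).

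Reads were next compared by the class of their transcript model. Annotated models held 67.6% of mouse reads in replicate 1 and 62.8% in replicate 2 (65.2% ± 3.34, n = 2). Models that matched an annotated transcript in part held 12.9% ± 3.01, new combinations of annotated splice sites 3.38% ± 0.112 and models with a new junction 8.19% ± 5.53. The tables put the same Aldoa junctions in different classes, so that this 1 model was 10.75% of incomplete reads in replicate 1 and 29.17% of new-combination reads in replicate 2, and the small SD of the latter class carries this. The last class held 12.1% in replicate 1 and 4.28% in replicate 2, and the leading Atp2a1 model alone held 97565 of the 129036 such reads in replicate 1 and 30697 of the 63212 in replicate 2. Antisense models held 2.32% and 5.75%, intergenic models 0.401% and 1.10%, and genomic models, which lie in genes but match no annotated transcript in part or by splice sites, 3.42% and 7.75%. Wilson 95% intervals per library spanned under 1 percentage point.

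**Figure D3:**
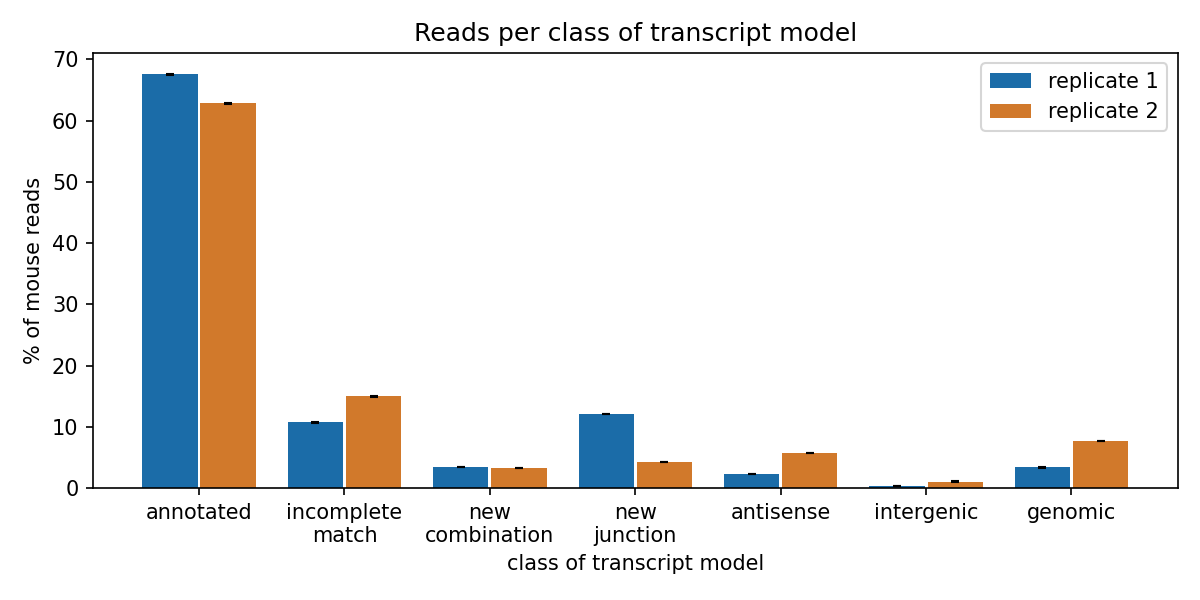
Share of mouse reads in % per class of transcript model and replicate, with Wilson 95% intervals too narrow to see at this scale. Annotated models hold 67.6% and 62.8%, and the antisense, intergenic and genomic classes are higher in replicate 2.

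Splice forms were read from a fixed panel of 38 muscle genes. Tpm1-205 held 94.3% ± 2.87 of Tpm1 reads (SD, n = 2; 27299 of 28356 and 34066 of 36940 reads), Tpm2-202 83.9% ± 7.74 of Tpm2 reads and Pkm-202 82.5% ± 8.45 of Pkm reads. An annotated 8-exon transcript of Pdlim3 held 76.8% ± 10.7, Slc25a3-206 76.5% ± 8.35, Fhl1-204 61.2% ± 3.49, Myl1-202 60.3% ± 0.602 and an annotated 12-exon transcript of Eno3 54.1% ± 2.71 of the reads of their genes. For other genes an unannotated model led. A 9-exon model of 1346 bases held 80.4% ± 4.13 of Aldoa reads, a 14-exon combination 50.7% ± 6.62 of Bin1 reads, an 8-exon model with a new junction 60.8% ± 7.45 of Pdlim5 reads and a 22-exon model 89.8% ± 5.57 of Atp2a1 reads. The deposited tables called the same Aldoa junctions an incomplete match in replicate 1 (12320 reads) and a new combination in replicate 2 (14236 reads). Tnnt3 was spread over many models, and the spliced model with the most reads in sum, an 11-exon combination, held 13.4% and 8.49%, beside 10-exon models with 13.2% and 7.55%, and with 7.35% and 8.64%. The leading model was annotated in 14 genes, a new combination in 2, a new junction in 3, an incomplete match in 8 and a genomic model in 11, and its median share was 57.4% ± 5.21.

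The leading isoform's share differed between the libraries most often through incomplete and genomic models. For Des, a group of overlapping single-exon models held 363 of 3300 reads in replicate 1 and 3944 of 5368 (73.5%) in replicate 2. The shares of such groups were 25.6% and 83.1% for Myom1, 19.7% and 76.5% for Ptp4a2 and 28.6% and 85.7% for Perm1, and those of the 3-exon Myh4 model were 5.70% and 63.1%. An annotated 18-exon transcript of Lonp1 held 86.4% and 27.5% of Lonp1 reads. Coq3, Gm29773, Dcaf6 and Rassf3 completed the 10 largest differences, and the largest Coq3 and Dcaf6 models are listed at 1 base. Fisher's exact test with Benjamini-Hochberg adjustment called 660 of 1834 genes, with the leading share lower in replicate 2 in 455 and higher in 205. With incomplete and genomic models left out, 42 of 1442 genes were called, and 40 of them were among the 660.

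Incomplete matches held more of the reads of genes with long transcripts. In genes with an annotated transcript under 1000 bases they held 6.10% of reads outside genomic models in replicate 1 (Wilson 95% interval 6.01 to 6.19) and 10.4% in replicate 2 (10.3 to 10.5). In genes of 6000 bases or more, among which is Myh4, they held 37.0% (36.5 to 37.5) and 66.6% (66.1 to 67.1). The longest bin exceeded the shortest 6.07-fold in replicate 1 and 6.40-fold in replicate 2. Without Myh4, left out after the data were seen, the longest bin held 26.4% and 33.8%, or 4.33-fold and 3.25-fold the shortest. The median share per gene in the longest bin was 10.5% in replicate 1 and 21.8% in replicate 2.

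Unannotated spliced models were compared between the libraries by their junctions. The model with the most reads was the 22-exon Atp2a1 model, with 97565 reads in replicate 1 (93.7% of the gene's reads) and 30697 in replicate 2 (85.9%). It lacks the annotated 18-base second exon (126462500 to 126462517) and extends the first exon by 26 bases to 126462779, and its other exons are those of the annotation. None of the 100355 and 32119 reads that span the second exon kept it, which allows a share of up to 0.00278% (exact 95% upper bound, both libraries). A 7-exon Tnni2 model followed with 3674 and 4819 reads, a 40-exon Myh4 model with 3501 and 765, a 5-exon Oaz1 model with 1528 and 2219 and a 6-exon Srl model with 1642 and 580. Models of Myl1 (8 and 6 exons), Ndrg2, Vdac3 and Mrpl33 made up the other 5 of the 10 with the most reads. The Mrpl33 model held 98.5% and 96.6% of the gene's reads, and the Oaz1 model 96.2% and 95.2%. Of 21826 unannotated models in replicate 1 and 20303 in replicate 2, 5913 were in both, in 2825 genes, and these held 88.7% and 71.9% of the reads of such models. The Atp2a1 model weighs on these shares, with 97565 of the 129036 new-junction reads in replicate 1 and 30697 of the 63212 in replicate 2.

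**Figure D4:**
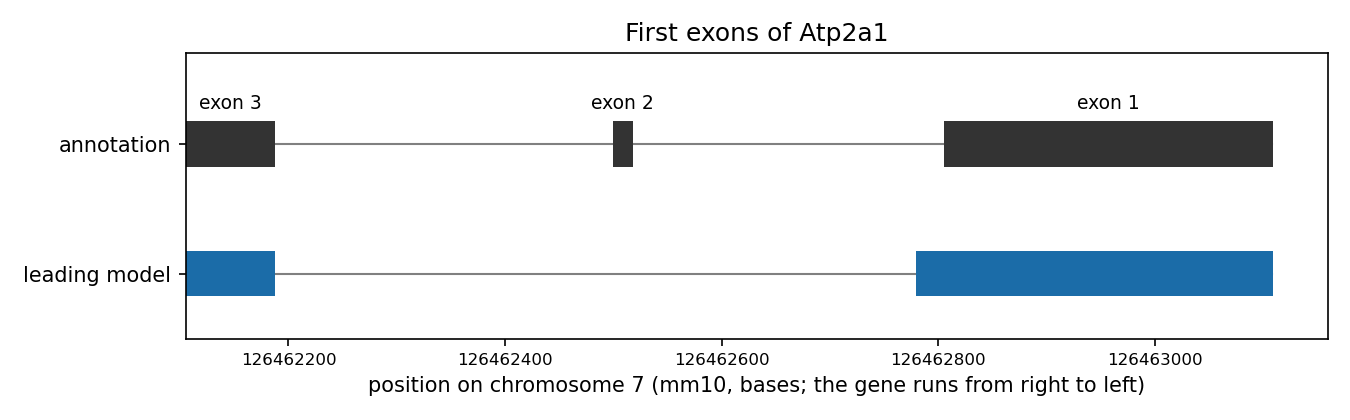
Exons 1 to 3 of Atp2a1 in the annotation and in the model that leads in both libraries, drawn to scale along chromosome 7 in bases, with the gene running from right to left and exon 3 at the left edge. The 18-base exon 2 is absent from the model, and its first exon ends 26 bases further into the intron.

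Antisense and intergenic reads were spread over many loci, and the 10 loci with the most reads held 20.3% of them in replicate 1 and 19.2% in replicate 2. A locus of 1317 bases opposite Klhl31 (chromosome 9, 77656522 to 77657838, minus strand) had 2865 reads in replicate 1 and 9514 in replicate 2, against 88 and 100 reads of Klhl31 itself. A locus opposite Gm26917 (chromosome 17, 39843013 to 39846245) had 1755 and 565 reads. Loci opposite Cdv3, Ptp4a2, Msrb3, Sdc4 and 2900097C17Rik had 209 to 281 reads in replicate 1 and 662 to 1433 in replicate 2. The intergenic locus on chromosome 4 (91851488 to 91851668) had 0 and 1661 reads and shares its last base with the edge of Gm12671, as the one beside Gm12033 does. Another intergenic locus, on chromosome 15 (103619061 to 103619240), had 93 and 694 reads. Of 26660 antisense or intergenic loci, 5820 (21.8%) had reads in both libraries, and single-exon models held 97.3% and 98.7% of antisense reads. How strand was assigned to single-exon reads is not given in the sources used here, so antisense reads cannot be told from sense reads of the opposite gene.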

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

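The tests of a CAST/EiJ variant and of the reading frame were chosen only after the Atp2a1 result was seen, as was the correction for length, and the other tests in this part were written before their results. The labels give a single group, so no biological explanation was tested for any pattern.

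Spike-in RNAs are outside the comparisons between genes, and drew attention because they carry reads in both libraries, 40775 in replicate 1 and 36684 in replicate 2, from 52 spike-ins in each. They bear on the first pattern, that short transcripts were higher in replicate 2 and long ones in replicate 1. Among 38 spike-ins of 273 to 1994 bases the slope of the log2 ratio per doubling of length was −0.62 (95% bootstrap interval −1.05 to −0.22), and −0.54 among mouse genes of that range. Spearman's rho of length and ratio was −0.52 (n = 38, two-sided permutation p 0.00089), and without the 2 spike-ins farthest from the median length the slope was −0.43 (−0.95 to −0.11). Of these spike-ins, 20 were of 500 to 1000 bases and 15 of 1000 to 1500. None was longer than 1994 bases, so the slope of longer genes is not covered. Their median log2 ratios in those 2 bins were −0.36 and −0.85, below those of mouse genes (0.62 and 0.27). Up to 1994 bases, the shared slope could come from size handling that differed between the library preparations. Broken RNA in the sample of replicate 2 may add to it, since the share of 3′ fragments was higher there by a median of 0.275 percentage points (0.120 to 0.419) over 1834 genes, but 54.3% of genes showed that direction, and damage to mouse RNA alone leaves the spike-in slope without a cause. That share covers only models labelled as the 3′ part of a transcript. Incomplete models labelled as neither end held 17.9% of incomplete reads in replicate 1 and 28.5% in replicate 2. Genomic models held 3.42% and 7.75% of mouse reads. Neither class enters the share, so its small size does not limit how much RNA was broken.

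The second pattern is the ratio of Myh1 to Myh4, which was lower in replicate 2 by a log2 difference of −2.43 (counting interval −2.55 to −2.30). The length trend gives 0.02 (0.0189), because both transcripts are near 6000 bases, so a trend on full transcript length is argued against. That value cannot exclude an effect of the size of the molecules read, since it was taken from full-length models. The 460-base model held 5.70% of Myh4 reads in replicate 1 and 63.1% in replicate 2. Incomplete reads shared between near-identical myosin genes could account for part. With annotated models alone the difference was −0.84 (−1.09 to −0.59), on either side of the bound of 1 set beforehand, so the test leaves this open. It also cannot separate reads placed on the wrong gene from true 3′ fragments of Myh4.

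The third pattern is the lack of the 18-base second exon in Atp2a1 reads. A short exon lost when reads were placed on the genome is a candidate explanation: outside Atp2a1, 15 of 130 exons of at most 30 bases (11.5%, exact interval 6.60 to 18.3) were mostly skipped through unannotated junctions, against 4 of 14783 exons of 51 to 200 bases (0.0271%), a ratio of 426.4. The 7-base exon of Tnni2 and the 14-base exon of Tnnt3 were skipped by 100% and 99.96% of spanning reads. Among tested exons of 17 to 19 bases, that of Hacd1 (19 bases) was skipped by 100%, and the others were mostly kept. Those of Trdn and the paralogue Atp2a2 (18 bases) were skipped by 0.8% of 375 and 9.72% of 72 reads. Those of Rnf5 and Ik (19 bases) were skipped by 6.94% of 72 and 0% of 55. For Sugt1 (17 bases), 3 reads skipped the exon and 29 kept it in replicate 1, with 6 and 52 in replicate 2. The ratio for exons of at most 30 bases therefore cannot decide whether an 18-base exon is lost. A variant on the CAST/EiJ allele alone is argued against, since 0% of spanning reads kept the exon and the other allele would keep it. A splice form that keeps the reading frame is argued against by a net change of 8 coding bases, if the deposited exon ends are exact.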

How the results depend on the processing

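Removal of the length trend, the restriction to genes with a known length and leaving out Myh4 were chosen only after the data were seen, and the other alternatives were planned. Among the results that answer a comparison, 39 values under settings fixed beforehand kept within the limits given for the processing and 22 moved, and 2 kept and 3 moved under added settings. Among single lists, genes and classes, 118 kept and 38 moved under settings fixed beforehand, and 9 kept and 15 moved under added ones. Some of the kept values could not have moved. TMM shifts all list medians by the same amount, which is under the random SD of every list but the splicing panel. Other pseudocounts cannot change Spearman's rho. Direction was not the same throughout: 982 of the 987 genes called both ways kept it when classes were restricted, and the list medians that changed sign are given with the results. Leaving out replicate 1 or 2 gives the other's value, which lies within 1 SD of a mean of 2 by construction, so it tests nothing, and the 48 and 126 such values are not in these counts. Values over 1.5 times apart between the replicates include Myh1 (14.7% and 3.15%), Myh2 (2.53% and 1.43%), the antisense (2.32% and 5.75%), genomic (3.42% and 7.75%), intergenic (0.401% and 1.10%) and new-junction (12.1% and 4.28%) classes, and in CPM the lists for slow sarcomere (959 and 2380.5), mitochondrially encoded (2795 and 13266), calcium handling (120760 and 50955), matrix (6458 and 2052), nuclear oxidative phosphorylation (23414 and 40300), adipocyte (155 and 405), immune (155 and 102), smooth muscle (260.5 and 133), satellite cell (44.4 and 21.1), immediate early (176 and 65.5), atrophy (955 and 417) and splicing panel genes (195865 and 128255). The cause of the changes below was not tested unless the alternative's construction gives it.

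Counting annotated, new-combination and new-junction models alone gave a Pearson r of 0.858, a Spearman rho of 0.816, 1.08% for Myh7, log2 ratios of 6.32 for Myh4 over Myh7, 8.84 for Mylpf over Myl2 and 6.80 for Tnnt3 over Tnnt1, and 47390.1 CPM for glycolytic genes. List levels over 1.5 times apart from those with all models were 5666.2 CPM for myosin heavy chains, 180.5 for tendon, 1032.3 for slow sarcomere and 178 for adipocyte genes. It removes the 460-base Myh4 model and the 776-base Tnnt1 model. Without a filter on low counts r was 0.901 and rho 0.857, and r was 0.857 with a pseudocount of 0.5 and 0.900 with 5. Adjusted p alone called 2412 genes. Removal of the length trend left 699 genes, or 673 with lengths from annotated models alone, against 1394 of the same 8120 genes uncorrected, while TMM gave 1343 and DESeq2 size factors 1374.

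As shares of models instead of reads, annotated models were 18.5%, incomplete matches 22.8% and antisense models 16.2%, and annotated models held 69.3% of reads in models with at least 5 reads. The ratio of incomplete shares between the longest and shortest bins was 5.59 with bins of 500 bases and 3.90 with quintiles, which widen the longest bin, and 3.79 without Myh4. Leaving out incomplete and genomic models left 42 genes with a different leading share. Unannotated models in both libraries numbered 2393, 852 and 436 at 2, 5 and 10 reads, a stricter count by construction. TMM shifts every ratio alike and cannot change the 8 lists outside the random range. They were 7 of 19 with members of at least 50 reads, 11 with restricted classes and 11 with the length trend removed, with the lists gained given with the results. In the latter the median of the splicing panel was −0.02 and no longer outside, and immediate early genes dropped out with restricted classes. The simulated test called 43.5% of genes changed 2.5-fold, and what limits it was not separated.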

Other observations

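The values in this part were looked at only after the data were seen, and no explanation for them was tested. Single-exon models of some called genes adjoined a model of another gene or locus. Of 31 genes that were called higher in replicate 1 and were led by an annotated single-exon model, 11 had reads of another gene or locus in a single-exon model that shared an end base with theirs, and 7 of these were under 2-fold once the reads were added. Gm13340 went the other way, from a log2 ratio of −5.76 to 2.53. The corresponding numbers were 17 of 73 genes, with 6 under 2-fold, among those higher in replicate 2. Some of these neighbours, such as mt-Atp6 and mt-Co3, are annotated genes that share a base. The most reads in an adjoining model were at Gm12671, with 1775 and 879 reads of its own and 0 and 1661 in the adjoining locus, where the log2 ratio went from −1.42 to 0.11.

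Antisense reads did not follow the reads of their host gene. Across genes with at least 10 reads, Spearman's rho between the antisense and the sense count was 0.0459 in replicate 1 (6234 genes, 2378 with antisense reads) and 0.0165 in replicate 2 (6294 genes, 3426 with antisense reads), where genes are not independent replicates. The ratio of antisense to intergenic reads was 5.78 and 5.24.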
